A study of Mus musculus with 4 samples.

How the data were processed

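RNA-seq was done on CD4+CD8+ double-positive (DP) thymocytes sorted from C57BL/6 mice. The 4 libraries fall into 2 groups of 2, per the labels: WT mice carrying floxed Chaf1b alleles without Cre, and KO mice carrying the same alleles with Cd4-cre, a transgene with Cre recombinase under Cd4 control. Per the labels' protocols, messenger RNA was selected with poly-T beads and libraries were made with a kit that does not mark strand. Per the submitters' processing notes, reads were handled with FastQC, Trim Galore 0.5.0, HISAT2, featureCounts 1.6.4 and DESeq2 on the GRCm38 genome build. Versions of the other tools are not given in the sources used here. The deposited values are raw fragment counts per gene, made with featureCounts 1.6.3 per the file headers, a version that differs from the notes. The header's command counted paired fragments over exons of the Ensembl 98 annotation without strand, and had no option for multi-mapped fragments or for fragments over several genes, so reads shared by near-identical copies or by overlapping genes were left out of the deposited counts. Values of such genes are therefore uncertain, and sense and antisense transcripts cannot be told apart. The deposited table also gives a gene length in bases, per the file headers, which entered only a check of length bias.

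The table holds 56239 genes. Gene symbols, transcript biotypes and sequences came from GENCODE M21 on GRCm38, an earlier release than the authors' annotation; 55154 IDs matched (98.1%), and the 1085 others took at most 0.0408% of any library's counts. Coordinates are those of the deposited table. Library totals ran from 21068760 to 27369874 counts. A count of 0 allows up to 3 counts, which is 0.110 to 0.142 CPM (counts scaled to library size) depending on the library. Intervals for shares are exact (Clopper-Pearson) 95% intervals; they and the floors cover counting error only, since PCR copies are not independent molecules. The replicates of a group were separate libraries: a chi-square statistic over genes was 11.3 per degree of freedom between the WT libraries and 51.2 between the KO libraries. The labels do not say how many mice gave each library. Within a genotype the replicates differed in sex by Xist and the Y-linked genes, so they came from different animals. The p-values measure the spread between these libraries.

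Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16's filterByExpr (15070 genes, holding 99.9% of the counts in the library that lost most), scaled with TMM factors (0.919 to 1.04) and tested with edgeR's quasi-likelihood F test, KO minus WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. This planned test had no covariate and 2 residual degrees of freedom. Replicate 1 of each genotype expressed Xist and replicate 2 the Y-linked genes, so the replicate number separates the sexes; a second fit with the replicate number as a term, called the sex-term fit here, is given beside the planned test. It was planned as an alternative before the data were examined and moved into the results after the sex-linked transcripts had been seen. It leaves 1 residual degree of freedom, and in it sex and any day or batch shared by a replicate number are the same thing. Differences within a sex are called the female pair and the male pair; they are differences of log2 CPM with a prior count of 2.

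The planned rule for named genes took Chaf1b and Chaf1a; up to 10 genes a direction with the largest change among those past the threshold, with both KO libraries on the same side of both WT libraries and a mean of at least 5 CPM, leaving out models without a given symbol, pseudogenes, receptor segments and sex-linked control genes; up to 4 members of each gene list past the threshold, or else the 2 most highly expressed; and a fixed set of DP and iNKT genes, of which 1 is not reported here. The planned test left no gene for the second part, so that part and the list part were also applied to the sex-term fit, a decision made after the values were seen; clone-numbered models were left out there too. Genes around Gm33707, Neat1, Malat1, Eno1 and Alb are named outside the rule, after their values were seen.

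The 30 gene lists were fixed before the data were examined. They were tested with limma 3.58.1's camera on log2 CPM with a preset inter-gene correlation of 0.01 and adjustment over the lists. Lists of liver transcripts and of snoRNA host genes were added after the values were seen and were not entered in that test; a second liver list was then written without a look at its values and took the first one's place in the test of liver RNA. The edgeR and camera steps were tested on simulated counts whose means and dispersions came from the sex-term fit to these libraries. With 200 of 15070 genes changed, the planned test recovered 37.0% of 2-fold and 91.0% of 4-fold changes with 0 false calls among 128. The sex-term fit recovered 83.0% and 98.0% with 9 false calls among 190. Every simulated gene kept a replicate difference shared by both genotypes, and no library deviated on its own. The simulation therefore favoured the sex-term fit by design and does not show which fit suits the real libraries. A list shifted by 0.5 on the log2 scale was called by camera, as was 1 other of the 30 lists. Simulated genes were drawn independently of each other. The run therefore cannot show how often camera calls unshifted lists whose members move together. Alternatives were RLE, upper-quartile and no scaling factors, other count filters, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate block, leaving out each library, leaving out receptor segments and mitochondrial genes, thresholds of 0.01 and 0.1, a test against a 1.5-fold change (glmTreat), and other set tests. Similarity of Gm33707 to other transcripts came from blastn with an E-value limit of 1e-50. Nothing in the deposited table was left out except genes under the count filter.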

Results

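Chaf1b encodes the p60 subunit of chromatin assembly factor 1, the chaperone that places histones H3 and H4 on newly copied DNA. The study's title places it in the early development of invariant natural killer T (iNKT) cells, which arise from DP thymocytes, and the comparison asks how DP thymocyte transcripts differ when Chaf1b is deleted by Cd4-cre. There were 2 WT and 2 KO libraries, with 23215539 and 27369874 counts for WT replicates 1 and 2 and 24688653 and 21068760 for KO replicates 1 and 2. In both genotypes replicate 1 came from female cells and replicate 2 from male cells: Xist had 47368 and 47301 counts in WT and KO replicate 1 against 8 and 12 in replicate 2, and Ddx3y had 2 and 14 counts in replicate 1 against 5384 and 3311 in replicate 2.

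The targeted transcript was lower in both KO libraries. Chaf1b (ENSMUSG00000022945, chromosome 16, 93883901 to 93906115, GRCm38) stood at 27.9 and 31.7 CPM in the WT libraries and at 12.2 and 14.8 CPM in the KO libraries, or 29.8 ± 2.75 CPM in WT against 13.5 ± 1.86 CPM in KO (SD, n = 2). The log2 difference was -1.19 in the female pair and -1.10 in the male pair. Counts were taken over every exon of the gene, and a conditional allele removes only some exons, so reads outside the deleted part can remain. With edgeR the log2 fold change was -1.14 ± 0.16 (SE) with an adjusted p of 0.267 in the planned test and -1.15 ± 0.17 with an adjusted p of 0.0172 in the sex-term fit. Its partner Chaf1a, the large subunit, had 53.7 ± 0.924 CPM in WT and 64.4 ± 14.3 CPM in KO (SD, n = 2), a log2 fold change of 0.26 ± 0.17 (SE) that did not pass the edgeR threshold (adjusted p = 0.442). Of the 23 measured members of the list of histone chaperones, Chaf1b was the only one to pass in the sex-term fit, and also the only one when p was adjusted over the list alone.

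**Figure D1:**
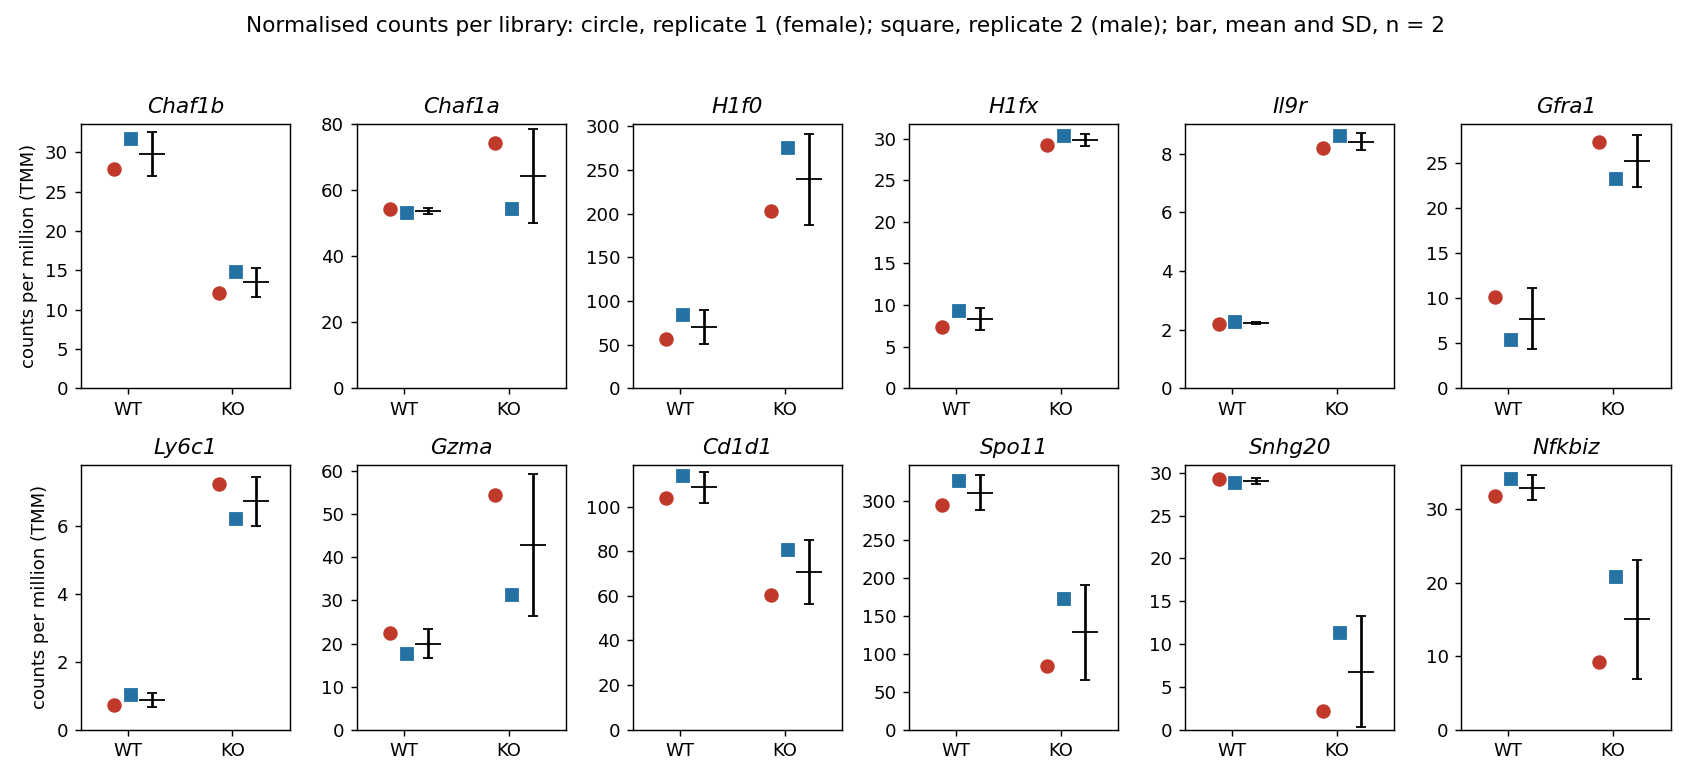
Normalised counts (CPM, TMM-scaled, linear axes from 0) of 12 genes in each library; circles are replicate 1 (female), squares are replicate 2 (male), and bars give the mean and SD of each genotype (n = 2). Chaf1b lies between 12.2 and 14.8 CPM in KO against 27.9 to 31.7 CPM in WT, while H1f0 lies between 203 and 276 CPM in KO against 56.4 to 84.3 CPM in WT.

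Across the 15070 tested genes, the numbers called higher and lower in KO depended on the fit and the threshold. The planned edgeR test called 1 gene higher (the pseudogene Gm33707) and 0 lower, although 2535 genes had an unadjusted p under 0.05 (1226 higher, 1309 lower) where 754 would be expected by chance. With the sex term, edgeR called 152 genes higher and 331 lower in KO. It called 5 higher and 2 lower at an adjusted p under 0.01, and 5 higher and 1 lower against a 1.5-fold change (glmTreat). DESeq2 without that term called 210 higher and 310 lower, and limma-voom without it called 1 higher and 0 lower. Among the genes called with the sex term, the change was larger in the female pair for 128 of the 152 higher and 324 of the 331 lower genes. Library-total scaling reduced the calls to 26 higher and 119 lower, so that the share of higher calls was 17.9% in place of 31.5%, and a robust dispersion estimate in edgeR left 29 higher and 47 lower.

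**Figure D2:**
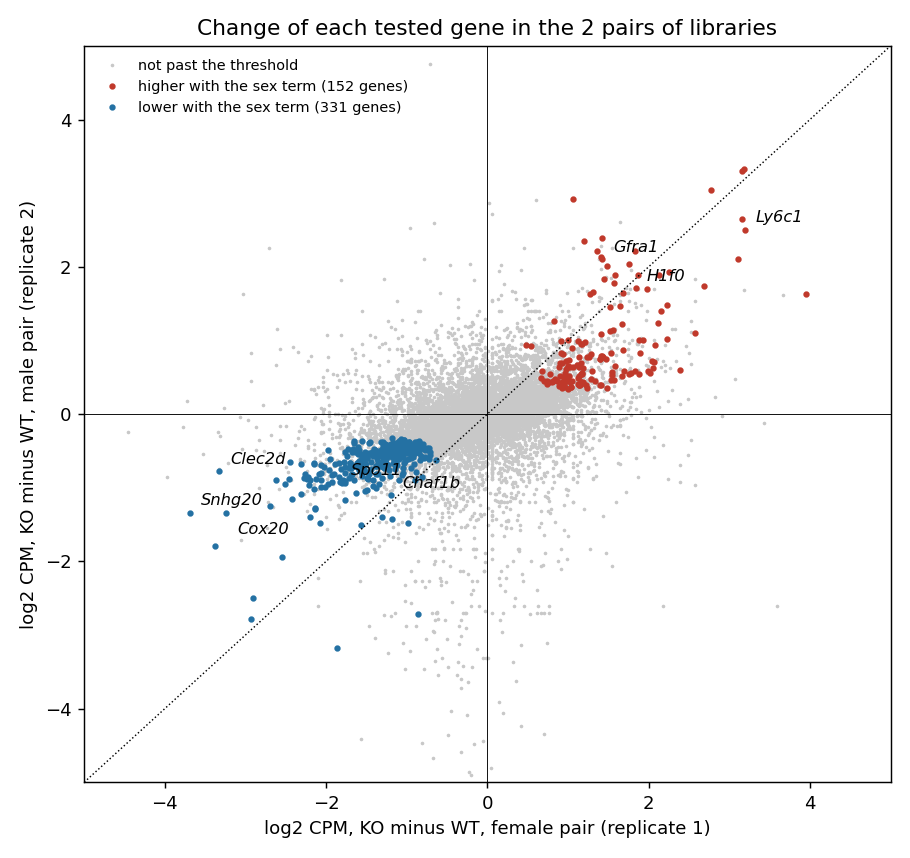
Log2 difference in CPM, KO minus WT, of each tested gene in the female pair (x axis) and the male pair (y axis); red and blue points are the 152 genes higher and 331 genes lower with the sex term, grey points the rest, and the dotted line marks equal change. Axes end at 5 and -5, which leaves 4 genes outside. Chaf1b sits close to the dotted line (-1.19 and -1.10), whereas Snhg20 sits far from it (-3.68 and -1.34).

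The 10 higher genes taken by the naming rule from the sex-term fit included 2 linker histone genes, 3 receptor genes and 3 mitochondrially encoded genes. H1f0, which encodes the linker histone H1.0 of slowly or non-dividing cells, rose in the sex-term fit from 70.4 ± 19.8 to 239 ± 51.6 CPM (SD, n = 2; log2 fold change 1.78 ± 0.15, SE; edgeR adjusted p = 3.04e-04). H1fx, which encodes the linker histone H1.10, rose from 8.33 ± 1.34 to 29.8 ± 0.761 CPM (log2 fold change 1.85 ± 0.18, edgeR adjusted p = 0.00144). Exons of both, and of Gfra1 and Il12rb2 named next, overlap other annotated transcripts, so their counts leave out shared reads. Il9r, the interleukin-9 receptor, rose from 2.23 ± 0.0447 to 8.40 ± 0.286 CPM, and Gfra1, a co-receptor for the growth factor GDNF, from 7.73 ± 3.40 to 25.3 ± 2.91 CPM. Il12rb2, a chain of the interleukin-12 receptor, rose by a log2 fold change of 1.58, Uaca by 1.47 and Slc23a4 by 1.46. The mitochondrially encoded genes were mt-Nd3, mt-Tn and mt-Tc (log2 fold changes of 1.35, 1.39 and 1.52). None of the 30 measured replication-dependent histone genes passed either test, but most of these transcripts lack the poly(A) tail by which the libraries were selected. Their median log2 difference was 0.14 in the female and -0.05 in the male pair. Hist2h2be, for example, had a log2 fold change of 0.17 (edgeR adjusted p = 0.551 with the sex term).

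The 10 lower genes taken by the naming rule from the sex-term fit were 3 noncoding host transcripts and 7 coding genes. Snhg20, a host transcript of small nucleolar RNA, fell from 29.1 ± 0.385 to 6.77 ± 6.46 CPM (SD, n = 2; log2 fold change -2.39 ± 0.40, SE, sex term; edgeR adjusted p = 0.0196). Snhg5 fell from 39.7 ± 1.35 to 14.2 ± 9.68 CPM (log2 fold change -1.64), and Mir17hg, the host of a microRNA cluster, had a log2 fold change of -1.50. Cox20, needed for assembly of cytochrome c oxidase, had a log2 fold change of -2.21, and Clec2d, a lectin-like ligand of an NK receptor, one of -1.97. The other genes were Tmem191c (-1.68), Phf1, an accessory subunit of polycomb repressive complex 2 (-1.53), Ppp2r3d (-1.53), Dtx3 (-1.50) and Egfl8 (-1.46). Exons of Snhg20, Snhg5, Mir17hg, Cox20, Tmem191c, Phf1 and Egfl8 overlap other annotated transcripts, so their counts leave out shared reads and are uncertain. For Snhg20, Cox20 and Clec2d the KO libraries differed widely from each other, with Clec2d at 7.32 CPM in KO replicate 1 and 40.4 CPM in KO replicate 2.

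Few genes that define the DP stage passed the threshold. With 2 libraries per genotype, this does not show that the others stayed at WT levels. Of the 48 measured DP thymocyte genes, 2 fell in the sex-term fit and 0 rose (3 fell when adjusted over the list alone). The list's medians were 0.13 and 0.01 in the female and male pairs, with 23 genes higher in both pairs and 19 lower in both. Spo11, a meiotic gene also transcribed in DP cells, fell from 311 ± 22.9 to 128 ± 62.8 CPM (SD, n = 2; log2 fold change -1.37 ± 0.20, SE; edgeR adjusted p = 0.0172), and Cd1d1, which encodes the molecule that presents lipids to iNKT precursors, fell from 109 ± 6.89 to 70.6 ± 14.3 CPM (log2 fold change -0.64 ± 0.14, edgeR adjusted p = 0.0371). The log2 fold changes of Cd4 (0.10), Cd8a (-0.18), Rag1 (0.49), Bcl11b (0.37), Tcf7 (-0.09), Tcf12 (0.02), Runx1 (0.34) and Bcl2l1 (0.37) did not pass. Myb, on the DP, early iNKT and positive selection lists, went from 1160 ± 0.578 to 656 ± 169 CPM (SD, n = 2). Its log2 fold change of -0.85 fell just short of the threshold (edgeR adjusted p = 0.0536 with the sex term). Of the 42 measured genes of early iNKT development, 2 fell and 0 rose in the sex-term fit, Cd1d1 and its near-identical neighbour Cd1d2 (-1.54). Cd1d2 is annotated as a polymorphic pseudogene, and its counts are uncertain because reads common to both were not counted. The SLAM-family receptors Slamf1 (-0.02) and Slamf6 (-0.07), their adaptor Sh2d1a (0.06), Egr2 (0.24) and Myc (0.46) did not pass, and Zbtb16, the iNKT lineage factor, had 4 counts in KO replicate 1 and 0 in the other libraries. In the list of positive selection and T cell receptor signalling, 2 of 36 measured genes fell in the sex-term fit, the NF-kB regulators Nfkbiz (-1.23) and Nfkbid (-1.01), and 0 rose. Adjusted over that list alone in the sex-term fit, 5 fell and 1 rose. Neither this list nor the lists of DP and early iNKT genes was called by limma's camera (adjusted p = 0.531, 0.835 and 0.742).

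Transcripts of later or other T lineage stages were higher as groups. In limma's camera with the preset correlation, iNKT effector genes (14 measured; adjusted p = 0.00432), mature single-positive thymocyte genes (36 measured; adjusted p = 0.00213), double-negative stage and progenitor genes (14 measured; adjusted p = 0.0197) and genes of NK and gamma-delta T cells (6 measured; adjusted p = 0.0413) were higher in KO. Each of these lists had a limma camera adjusted p = 0.965 with an estimated correlation, so the calls did not hold there. At the preset correlation limma's camera did not call the mature list without KO replicate 2 (adjusted p = 0.0602), the NK list without KO replicate 1 or 2 (0.368 and 0.157) or the progenitor list without KO replicate 1 or WT replicate 2 (0.445 and 0.0844). In the sex-term fit 3 iNKT effector genes rose and 0 fell: Plac8 (log2 fold change 2.30), Il12rb2 and the granzyme gene Gzma (1.06). Of the mature genes 2 rose and 0 fell: Ly6c1, from 0.870 ± 0.216 to 6.72 ± 0.729 CPM (SD, n = 2; log2 fold change 2.93 ± 0.34, SE; edgeR adjusted p = 0.00397), and the transcription factor gene Foxo1 (0.70). Ly6c1 has close paralogs, so its count is uncertain. None of the progenitor genes and 1 NK or gamma-delta gene (Gzma) passed. Adjusted over the list alone in the planned test, 3 effector, 1 mature, 0 progenitor and 1 NK or gamma-delta genes were higher and none lower. Among the other cells that a sort could hold, the NK and gamma-delta list was thus called at the preset correlation. That call cannot tell such cells in the sort from a change in DP cells. The lists for B cells, macrophages and granulocytes, dendritic cells, erythroid cells, and thymic epithelium and stroma were not called. Their limma camera adjusted p were 0.715, 0.923, 0.715, 0.923 and 0.923. From the B-cell list 1 gene, Cd79b, rose in the sex-term fit (0.76).

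**Figure D3:**
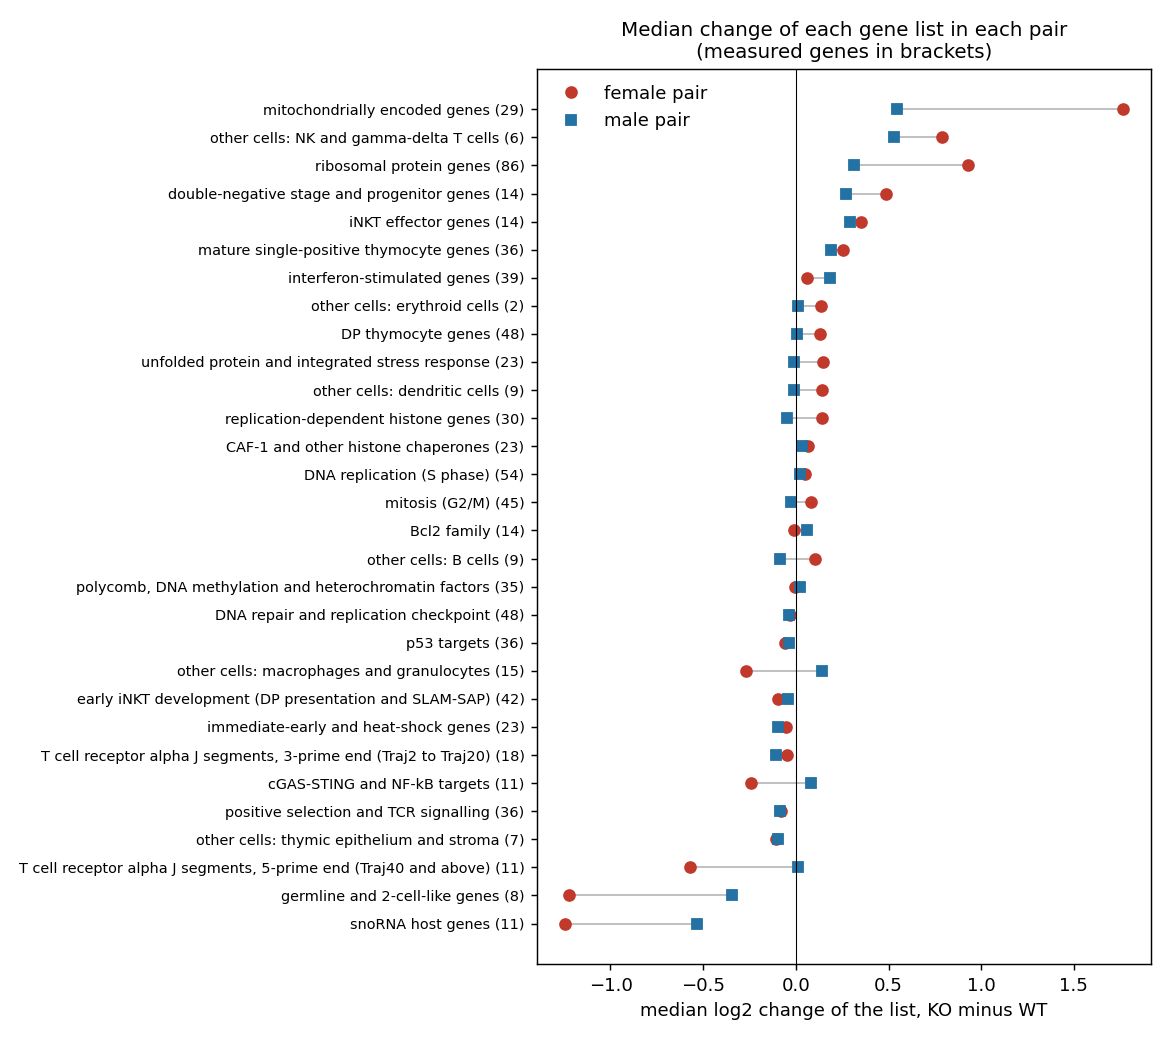
Median log2 difference, KO minus WT, of each gene list in the female pair (circles) and the male pair (squares), with the number of measured genes in brackets and lines joining the pairs of one list. Mitochondrially encoded genes lie at 1.76 and 0.55, ribosomal protein genes at 0.93 and 0.31, and snoRNA host genes, a list added after the values were seen, at -1.25 and -0.53.

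Ribosomal protein and mitochondrially encoded transcripts were higher in KO as groups. Of 86 measured ribosomal protein genes 82 were higher in KO in both pairs, with a median log2 fold change of 0.65 (limma camera adjusted p = 6.35e-17, but adjusted p = 0.965 with an estimated correlation). Of these genes 8 rose and 1 fell in the sex-term fit, and 57 were higher in the planned test when adjusted over the list alone. Rps29 rose by 0.85, Rps28 by 0.86 and Rpl39 by 0.73, while Rps10, which shares exons with a read-through transcript, fell by 1.37. Of 29 measured mitochondrially encoded genes 27 were higher in both pairs, with a median of 1.23 (limma camera adjusted p = 2.77e-11, but adjusted p = 0.965 with an estimated correlation). Of these genes 11 rose and 0 fell in the sex-term fit, and 19 were higher in the planned test when adjusted over the list alone, among them mt-Co2 (1.17 with the sex term). KO replicate 1 stood apart: mitochondrial transcripts took 3.30% of its counts (95% interval 3.29 to 3.31) and 2.03% (2.02 to 2.04) in KO replicate 2, against 1.33% (1.33 to 1.34) and 1.45% (1.45 to 1.45) in the WT libraries. Ribosomal protein transcripts took 4.94% and 3.60% of the KO counts against 2.86% and 2.91% of the WT counts. The 8 measured of 44 listed germline and 2-cell genes were lower as a group (limma camera adjusted p = 0.0463, and 0.0574 with the sex term). In the sex-term fit Xlr4a (-1.01) and Xlr4b (-0.81), near-identical X-linked copies, fell and 0 genes rose. The calls of single genes thus came from the same gene family. The list was not called without WT replicate 1, WT replicate 2 or KO replicate 1. That list, too, had a limma camera adjusted p = 0.965 with an estimated correlation.

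Lists for cell division and DNA damage were not called, and few of their genes passed the test over all genes. Calls of single genes in this paragraph come from the sex-term fit, and none of these genes passed in the planned test. Of the 54 S-phase genes 1 rose, Pola1, the catalytic subunit of DNA polymerase alpha (0.64), and 0 fell. None of the 45 mitotic genes passed (limma camera adjusted p = 0.715 for both lists). Adjusted over the list alone in the sex-term fit, 0 S-phase genes and 2 mitotic genes were higher, so Pola1 did not pass there. Mki67, a gene of dividing cells, stood at 882 and 792 CPM in WT and at 1862 and 953 CPM in KO replicates 1 and 2 (edgeR adjusted p = 0.140 with the sex term). Mitotic genes took 0.660% of the counts of KO replicate 1 against 0.539% to 0.556% in the other libraries. None of the 48 repair and checkpoint genes passed either (limma camera adjusted p = 0.923). Among 36 p53 targets Abhd4 rose (1.38) and the repair gene Ddb2 (edgeR adjusted p = 0.0208) and the pro-apoptotic gene Bax (-0.76) fell, while Cdkn1a, the p21 inhibitor of the cell cycle, had a log2 fold change of 0.94 that did not pass (edgeR adjusted p = 0.129 with the sex term). Bax was also the only one of 14 Bcl2-family genes to pass, and Bcl2 had a log2 fold change of 0.23. The p53 and Bcl2-family lists were not called (limma camera adjusted p of 0.923 and 0.835). In the list of polycomb, DNA methylation and heterochromatin factors 1 of 35 measured genes fell, the polycomb protein gene Cbx7 (-0.89). Atf4, of the integrated stress response, was the only one of 23 in its list to pass (-1.02), none of 23 immediate-early and heat-shock genes passed, and of 39 interferon-stimulated and 11 cGAS-STING and NF-kB genes Gbp7 (0.96) and Tmem173, which encodes STING (0.98), rose. None of these 5 lists, nor the lists of histone chaperones, of replication-dependent histones or of T cell receptor alpha J segments at the 5-prime (11 measured) and 3-prime (18 measured) ends or of 5 sex-linked control genes, was called by camera.

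The gene called in every fit above was Gm33707 (ENSMUSG00000102298), a processed pseudogene annotated on chromosome 3 at 60769887 to 60770455. It had 1424 and 1287 counts in KO replicates 1 and 2 and 0 in both WT libraries, which is at least 497-fold higher in KO against a floor of 3 counts per WT library (edgeR adjusted p = 0.00223 in the planned test). Its sequence is 89.2% identical to Eno1, the gene of a glycolytic enzyme, over 576 aligned bases. The model Gm38326, at 60788361 to 60794730, had 11 and 13 counts in KO and 0 in WT, and Mbnl1, a splicing regulator gene at 60472830 to 60629750, rose from 485 ± 17.6 to 848 ± 119 CPM (SD, n = 2; log2 fold change 0.80 ± 0.19, SE, sex term; edgeR adjusted p = 0.0464). Rap2b and the model Gm8325, on the other side, had log2 fold changes of 0.42 and 0.25 and did not pass. Gene calls in this comparison rested on 2 libraries per genotype, and without KO replicate 1 the test without a sex term called 171 genes higher and 349 lower, against 2518 and 2630 without KO replicate 2. The sex-term fit cannot be tested with a library left out, since no residual degree of freedom remains.

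**Figure D4:**
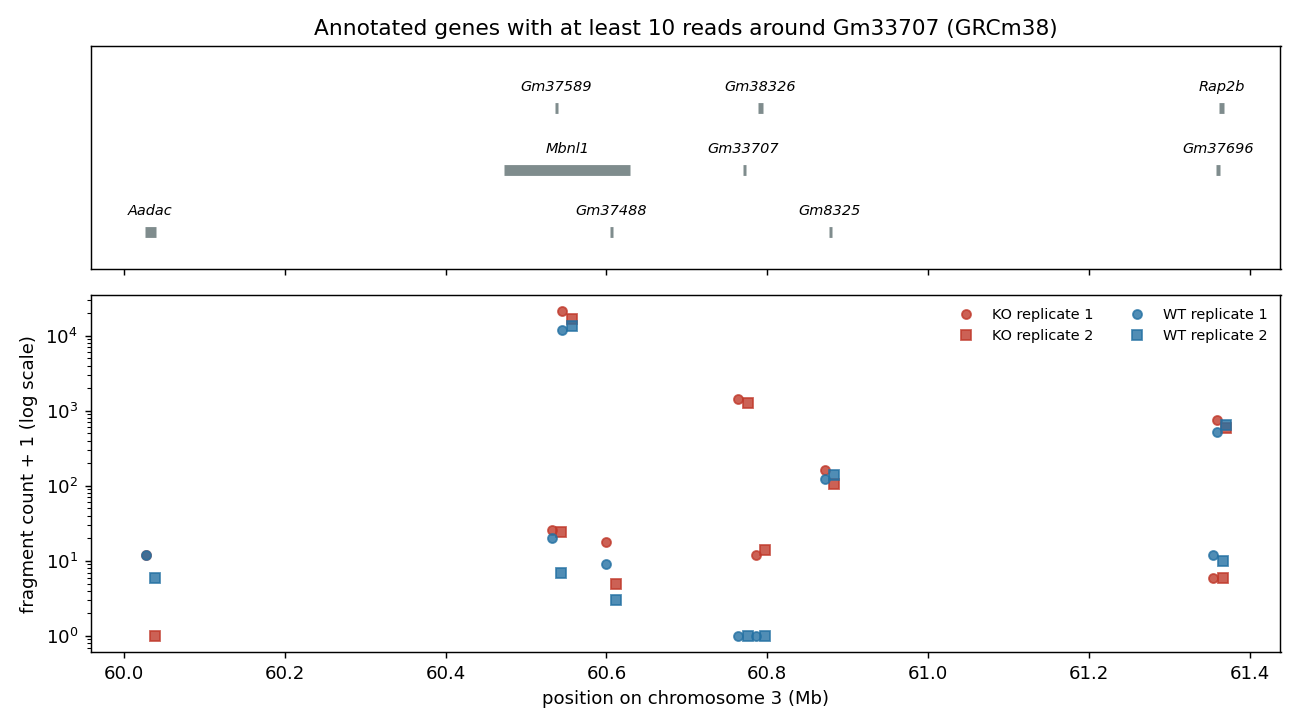
Upper panel, annotated genes with at least 10 counts within 1 Mb of Gm33707 on chromosome 3 (GRCm38, position in Mb); lower panel, each gene's fragment count plus 1 in each library on a log axis, KO in red and WT in blue. Gm33707 (1424 and 1287 counts) and Gm38326 (11 and 13 counts) have counts in KO and 0 in WT.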

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

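Chosen after the results were seen were the tests of Gm38326, of Eno1 reads and of KO replicate 1 alone. So were the tests of nuclear RNA and of the liver share of the calls, and the Poisson bound on silent genes. The others in this part were set before their values were seen. Differences between the sexes below come from 1 KO and 1 WT library each and were not tested.

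Traj2 differed in direction between the pairs, with a log2 difference of 0.31 in the female and -0.64 in the male pair. The median of the macrophage and granulocyte list was -0.27 in the female pair and 0.14 in the male pair.

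Gm33707 had counts in both KO libraries and 0 in WT. Reads of Eno1 counted at Gm33707 would give a similar ratio in every library. At the KO ratio of Gm33707 to Eno1 the WT libraries would hold 2412 reads (lower 95% Poisson bound 2317) where 0 were seen. This argues against Eno1 reads as the source. Other similar copies, such as the pseudogene Gm4735 (89.5% identical), were not tested in this way. An opening of many silent genes was not seen among those with 0 counts in both WT libraries. Of these, 2 had at least 10 counts in each KO library (Gm33707 and its neighbour Gm38326, upper 95% Poisson bound 7.22), fewer than the 10 named beforehand. The bound named for its absence, 3 times the reverse, could not be met because 0 genes showed the reverse. Genes with a few WT counts could not enter this count, so for them the question stays open. A candidate explanation that stays open is a local change on chromosome 3 carried by the KO mice; the counts of Gm38326 differed (exact binomial p = 1.74e-08, two-sided, reads taken as independent), but they prompted the idea and so do not test it. Whether it lies with the Cre transgene, with an inherited difference between the mouse lines or with the deletion of Chaf1b was not tested, because each KO library carries all of them.

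Mitochondrial and ribosomal protein transcripts were higher and snoRNA host transcripts lower in KO, a gap of 1.54 on the log2 scale between the medians of 115 and 11 genes. Removing the trends of GC content and gene length in each library left a gap of 1.53, which argues against these trends as the cause. The mitochondrial and ribosomal part was also higher in the male pair, which lacks KO replicate 1. Its median there was 0.325, above the central 95% of 10000 random lists matched on expression (-0.02 to 0.08), against 1.02 in the female pair. Random lists treat members as moving independently, while camera's estimated inter-gene correlations were 0.774 (ribosomal) and 0.793 (mitochondrial). The range therefore leaves out the spread between libraries of genes that move together. Whether the male pair's shift exceeds that spread was not tested, so KO replicate 1 alone as the source stays open. For the host transcripts (-0.532 in the male pair) it stays open as well, because their list was made from these values. Handling of RNA that differed between the genotypes, a lower share of nuclear RNA and the loss of Chaf1b stay open, and nuclear markers moved apart: Xist had a log2 difference of 0.0614 in the female pair and Malat1 -0.32 and -0.15 in the female and male pairs, above the upper quartile of the host transcripts (-0.72 and -0.36), while Neat1, at -1.69 and -0.83, lay below their medians (-1.25 and -0.53).

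Liver transcripts were present in sorted thymocytes, most of all in replicate 1: Alb had 6045 and 6597 counts in WT and KO replicate 1, 1605 in WT replicate 2 and 72 in KO replicate 2. All 25 transcripts of a liver list, chosen once such genes had been noticed, were higher in both replicate 1 libraries than in both replicate 2 libraries. On a second list of 40 liver transcripts this held for 34 (85.0%), short of the 90% set beforehand, so RNA from liver carried into the libraries stays possible and is not settled; the CD4+CD8+ sort would remove liver cells but not free RNA or mixing between libraries. Whether liver RNA entered the KO calls was not settled: 1 of 483 genes called with the sex term was on the first list (0.207%), but a list of 25 could reach no more than 5.18%, and its median was -3.31 in the male pair, with 10 genes lower when adjusted over the list alone.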

How the results depend on the processing

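The sex-term alternatives and DESeq2 without KO replicate 1 were added after the data were seen; the others were planned. Without a sex term, edgeR's counts of 1 higher and 0 lower were the same under the other scalings, the CPM filter, limma-voom, robust dispersion, both other thresholds, glmTreat and the removal of receptor segments and mitochondrial genes. They were 627 and 838 when every gene with a count was kept, 210 and 310 with DESeq2, and 152 and 331 with the replicate block, which is the sex-term fit. The cause was not tested. The replicate numbers are not stated to pair libraries, but the replicate differences of the genotypes correlated across genes (0.472, and 0.422 on autosomes). On autosomes without the first liver list the correlation was 0.387. Of 89 genes that edgeR called between the replicate numbers, 7 lay on the sex chromosomes and 22 were on that liver list, so the term takes up more than sex. Leaving out a library gave 1 to 2518 higher and 0 to 2630 lower genes (2 and 0 without WT replicate 1, 1 and 0 without WT replicate 2, 171 and 349 without KO replicate 1, 2518 and 2630 without KO replicate 2), where a lone library is assumed to vary like the other group; DESeq2 without KO replicate 1 gave 107 and 246. Chaf1b kept its direction throughout, at -1.30 to -1.01 with a library left out, and passed with DESeq2 (-1.14), with every counted gene kept (-1.15), with the replicate block (-1.15) and without either KO library. Its adjusted p was smallest with every counted gene kept (4.77e-07, edgeR) and largest with glmTreat, where it did not pass. Called gene lists numbered 7, 5 to 7 with a library left out, 6 with the replicate block, 3 without receptor segments and mitochondrial genes (3 lists then had no genes), 4 at a threshold of 0.01, 0 with an estimated correlation and 0 with fry. The iNKT effector and ribosomal protein lists were called under each setting except these last 2, and the mature list except these and without KO replicate 2 (adjusted p = 0.0602, limma camera). The germline list also lost its call by library totals, with every counted gene kept, with the block, with a prior count of 0.5 and without WT replicate 1, WT replicate 2 or KO replicate 1. The double-negative list lost its call under both other filters and without WT replicate 2 or KO replicate 1, and the NK list under the CPM filter and without either KO library. All 3 lost it at 0.01 and without receptor segments and mitochondrial genes. Calls were gained for interferon-stimulated genes without WT replicate 1 (adjusted p = 0.0101, limma camera) and for 3-prime J segments without KO replicate 1 (0.0338).

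With the sex term, 152 higher and 331 lower genes became 26 and 119 by library totals, which shift the median gene of the female pair to -0.16, 556 and 965 with every counted gene kept, 29 and 47 with robust dispersion, 5 and 2 at 0.01, 426 and 743 at 0.1, 5 and 1 against a 1.5-fold change, and 330 and 537 with GC and length trends removed. The cause was not tested. The other settings stayed within 1.5 times, and DESeq2 with the term shared 76 of the higher and 235 of the lower calls. No called value of the 120 named genes changed sign, while 46 of 2022 values without the term and 14 of 1544 with it did so, all uncalled. Calls were less stable than signs. The sex-term fit called 52 of the named genes. Across its alternatives, stricter thresholds included, calls were lost for 168 of the 1544 values and gained for 29. Counts of 0 allow up to 3 counts a library, which limits genes such as Zbtb16.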

Other observations

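Chaf1b itself was reduced to a similar degree in both KO libraries (log2 differences of -1.19 and -1.10), yet most lower genes fell further in the female pair. Some gains were close between the pairs, with H1f0 at log2 differences of 1.84 and 1.71, H1fx at 1.98 and 1.70 and Il9r at 1.86 and 1.89 in the female and male pairs, and others were far apart, with mt-Tc at 2.39 and 0.60, mt-Nd3 at 2.06 and 0.62 and Uaca at 1.88 and 1.01. Losses that were far apart included Snhg20 at -3.68 and -1.34, Dtx3 at -2.13 and -0.89, and Neat1, a nuclear noncoding RNA named after its values were seen, at -1.69 and -0.83. Across genes, which are not independent replicates, the log2 differences of the pairs had a Pearson correlation of 0.403 and a Spearman correlation of 0.521; the pairs share no library, and 72.2% of genes had the same sign in both.

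The tests of retained-intron transcripts below were chosen after the result was seen and that of decay-targeted transcripts before. Genes called lower with the sex term often had an annotated retained-intron transcript: 221 of 276 protein-coding genes (80.1%), against 45 of 106 higher (42.5%) and 6791 of 11459 uncalled ones (59.3%). Over all protein-coding genes the 7057 with such a transcript had a lower median than the 4784 without, by -0.0804 in the female and -0.0384 in the male pair, below the central 95% of 1000 random sets matched on expression in both (lower ends -0.00212 and -0.00360). Without the genes called with the sex term the differences were -0.0652 and -0.0323, again below the random sets in both pairs. Both runs used the libraries that prompted the idea, with sets matched on expression alone, so neither tests it independently. This small shift is consistent with lower levels of partly spliced RNA in KO, a hypothesis that gene counts cannot test, as exon and intron reads were not separated. Decay-targeted transcripts showed a shift in 1 pair only: among genes without a retained-intron transcript, the 712 with an annotated decay-targeted one differed from the other 4072 by -0.0612 in the female pair, below the range of random sets (lower end -0.0301), and by -0.0142 in the male pair, within it (-0.0204 to 0.0234).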
